A study of Caenorhabditis elegans with 12 samples.

How the data were processed

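RNA was sequenced from whole young adult C. elegans grown at 20 °C. Per the labels' protocols, eggs were hatched in M9 buffer to synchronize the animals, hermaphrodites and males were then separated, RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit from total RNA. The mutants carried the ok480 deletion allele of daf-18, which encodes the worm orthologue of the lipid phosphatase PTEN. Per the labels, the controls carried him-5(e1490), a mutation that raises the share of males among the offspring. The titles of the mutant samples name daf-18(ok480) alone, so mutants and controls may also differ in him-5 or strain background. Differences between them can therefore not be assigned to daf-18 alone. The labels describe 12 samples, 3 for each of the 4 combinations of genotype and sex. The deposited table used here holds 8 of these libraries, 2 for each group, and its control columns are named for the wild-type strain N2 while the labels name him-5. A column was given to a group by the genotype and sex in its name. Which of the 3 labelled samples of a group it holds is not stated, so the library numbers below are names and pair nothing. A further 4 columns in the other 2 of the 3 deposited tables have names that fit no labelled sample and were not used.

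The values are FPKM, fragments scaled by gene length and by library size, as deposited by the authors. Per the submitters' processing notes, Bowtie 0.12.2, StringTie and the genome build WBcel235 were used, and which of these tools made the table is not given in the sources used here. Each deposited FPKM multiplied by the gene length that the authors list was compared with the value of 1 read in its library: 100.0% of the 150029 values above 0 came out as whole reads, with a tolerance of 0.02 reads. The recovered totals were 17067648 to 18121950 reads per library. The denominators of the deposited FPKM were equal to a median-of-ratios factor multiplied by the geometric mean of the library totals, at a ratio of 1.0 in each library, so a scaling between libraries was already in the values. The table lists 46589 genes, 20528 of them protein-coding, and 22998 had a value above 0 in at least 1 library. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart, and members of families with near-identical copies, such as major sperm proteins, histones and collagens, are uncertain. The table also holds a few gene names altered by spreadsheet software. Coordinates are those of the deposited table. Of 17480 protein-coding names also found in the Ensembl 115 annotation of the same build, 12.1% had the same start and end, 90.9% had both ends within 1000 bases and 99.97% were on the same chromosome.

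The comparisons, gene lists, rule for named genes and the alternatives listed as set in advance were chosen before the data were examined. The FPKM were transformed as log2(FPKM + 1), and a fold change is therefore on that scale, which understates the change of genes with low values. Genes with an FPKM of at least 1 in at least 2 libraries were kept, leaving 16038 genes of which 15114 were protein-coding. A model with 1 mean per group was fitted over all 8 libraries with limma 3.58.1 in R 4.3.3 with an intensity trend and empirical Bayes, leaving 4 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05. The 5 comparisons were mutant against control in hermaphrodites, mutant against control in males, the difference between these 2 changes (the interaction), male against hermaphrodite in controls, and male against hermaphrodite in mutants. Errors of means are standard deviations, and errors of log2 changes are standard errors from the same limma model. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

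The 33 gene lists were tested with limma's camera, 2-sided, with a preset correlation of 0.01 between genes, against all other tested genes, with Benjamini-Hochberg adjustment over the lists of a comparison. They cover DAF-16 class I and class II genes, insulin/PI3K pathway components and insulin-like peptides, vitellogenins, major sperm proteins, sperm genes, oocyte genes, general germline genes, cell cycle genes and early embryonic genes. They also cover cuticle collagens, moulting genes, hedgehog-related genes, fatty acid synthesis, lipolysis and fatty acid oxidation, innate immune genes, heat shock genes, and antioxidant and detoxification genes. Further lists hold genes of male neurons and the male tail, seminal fluid, sex determination, neuropeptides, pan-neuronal genes, muscle, intestine, the hermaphrodite somatic gonad, coelomocytes with excretory system and pharyngeal gland, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, the mitochondrial genome, histones and ribosomal RNA. They name 1184 of the listed genes, and 6 of their entries matched no listed name. Lists with at least 5 tested members were tested, which leaves out the seminal fluid list with 4 members. Camera with a correlation estimated from each list, and fry, which asks whether the members of a list move 1 way on balance without comparing them with other genes, were run as alternatives set in advance. With an estimated correlation no list was called over all libraries, on the compared groups alone, or without the libraries labelled control hermaphrodite 2 and control male 2. List calls in the other fits, including those that leave out 1 library, used the preset correlation alone.

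Genes were named by a fixed rule. For a genotype comparison it takes the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the 2 groups. For the interaction and the sex comparisons it takes 5 per direction. For a called list it takes the 4 members with the smallest p-values, of which some are given as examples, and for other lists up to 2 members with the highest mean FPKM. After the data were examined, the same rule was applied to fits without the library labelled control hermaphrodite 2 and the library labelled control male 2, and to the sex comparison in mutants fitted on the mutant libraries alone. Genes named from those fits were chosen after their values were seen.

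The limma step was tested on simulated data before use. The genotype comparison in hermaphrodites was simulated 3 times, each with 200 changed genes among 15576 to 15624 tested. Every gene was given the median spread observed in its group, so differences in spread between genes were not simulated. Of the changes, 2% of 2-fold, 46% of 4-fold, 71.3% of 8-fold and 88.7% of 16-fold changes were recovered. With the spread of the mutant groups in all groups and 15499 to 15526 genes tested, 96% of 2-fold changes were recovered. Camera called the shifted set of 30 genes in 3 of 3 simulations under both spreads. The simulated genes varied independently, while the correlation estimated over all libraries was 0.98 for the oocyte genes. The simulations therefore do not show how camera behaves on correlated lists.

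Alternatives set in advance were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, no intensity trend, robust empirical Bayes, a fit on the compared groups alone, and leaving out each library in turn. Added after the data were examined were scaling each library by its own total, library weights estimated by limma, limma voom on the recovered whole reads, protein-coding genes alone, and leaving out both doubted control libraries. In a fit that leaves a group with 1 library, that library is assumed to vary like the other groups. Each genotype comparison has 2 libraries per group, too few for a count over other splits of the samples. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. Read totals are depth, and intervals from them would cover counting error only.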

Results

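Transcript levels were measured in whole young adult worms in 8 libraries, 2 each of control hermaphrodites, control males, daf-18 mutant hermaphrodites and daf-18 mutant males. The libraries held 17067648 to 18121950 reads, and 13568 to 14802 genes reached at least 1 FPKM in a library. Across genes, which are not independent replicates, log2 values correlated at r = 0.988 between the libraries of mutant hermaphrodites and at r = 0.98 between those of mutant males. The control hermaphrodite libraries correlated at r = 0.87 and the control male libraries at r = 0.754. The library labelled control male 2 correlated at r = 0.918 with mutant hermaphrodite library 1. The median standard deviation between the libraries of a group was 0.44 in control hermaphrodites, 0.72 in control males, 0.08 in mutant hermaphrodites and 0.14 in mutant males on the log2 scale. Each pair differed by more than sampling noise, with a chi-square per degree of freedom of 4.03 to 489.6, so each library was counted as 1 replicate.

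daf-18 itself (T07A9.6, chromosome IV, 419987 to 425173, minus strand, WBcel235) was detected in all 8 libraries. It encodes a lipid phosphatase, the orthologue of PTEN, that opposes the PI3 kinase AGE-1 below the insulin receptor DAF-2. Its level was 137.6 and 35.9 FPKM in the libraries labelled control hermaphrodite 1 and 2, and 33.98 and 266 FPKM in those labelled control male 1 and 2. It was 90.3 ± 0.679 FPKM in mutant hermaphrodites and 53.0 ± 1.78 FPKM in mutant males (SD, n = 2). The log2 difference between mutants and controls was 0.35 ± 0.99 in hermaphrodites (limma, Benjamini-Hochberg adjusted p = 0.963) and -0.84 ± 0.99 in males (adjusted p = 0.758), both smaller than the spread between control libraries. Without the libraries labelled control hermaphrodite 2 and control male 2 it was -0.60 in hermaphrodites and 0.63 in males. That fit has 1 control library in each sex, so it holds no spread between control libraries. Over all alternatives the adjusted p ran from 0.0409 to 1 in hermaphrodites and from 0.0604 to 1 in males. The values are summed over the whole gene, listed with a length of 3353 bases, and the part removed by the deletion is not given in the sources used here, so the level does not check the labels.

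Germline and moulting markers set the libraries labelled control male 2 and control hermaphrodite 2 apart from the other 6. The major sperm proteins, which form the sperm cytoskeleton and signal oocyte maturation, had a geometric mean of 1331 FPKM in control male 1 and of 908 and 834 FPKM in the mutant males, but of 63 FPKM in the library labelled control male 2. The oocyte genes, which include eggshell components, stood there at 428 FPKM, above the 29.9 to 202 FPKM of the 4 hermaphrodite libraries. The vitellogenins, which encode yolk proteins, stood at 769.9 FPKM against 10.98 to 268 FPKM in those hermaphrodite libraries. They stood at 70.98 FPKM in control male 1 and at 113.4 and 54.77 FPKM in the mutant males. Oocyte genes stood at 38.98 FPKM in control male 1 and at 62.1 and 46.7 FPKM in the mutant males. Yolk and oocyte transcripts were therefore present in every male library. The list of male neurons and the male tail stood at 1.21 FPKM in the library labelled control male 2, at 4.84 FPKM in control male 1 and at 5.71 and 5.33 FPKM in mutant males. It stood at 1.35 and 1.34 FPKM in the mutant hermaphrodites, above control male 2, and at 0.587 and 0.783 FPKM in the control hermaphrodites, so the mutant hermaphrodite libraries hold male transcripts too. In the library labelled control hermaphrodite 2 the moulting genes, active when a new cuticle is made, stood at 58.4 FPKM against 8.94 to 9.94 FPKM in the other 3 hermaphrodite libraries. Its oocyte genes stood at 29.9 FPKM against 189 to 202 FPKM. These 2 libraries are called the doubted control libraries below, and each comparison was also fitted without them.

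**Figure D1:**
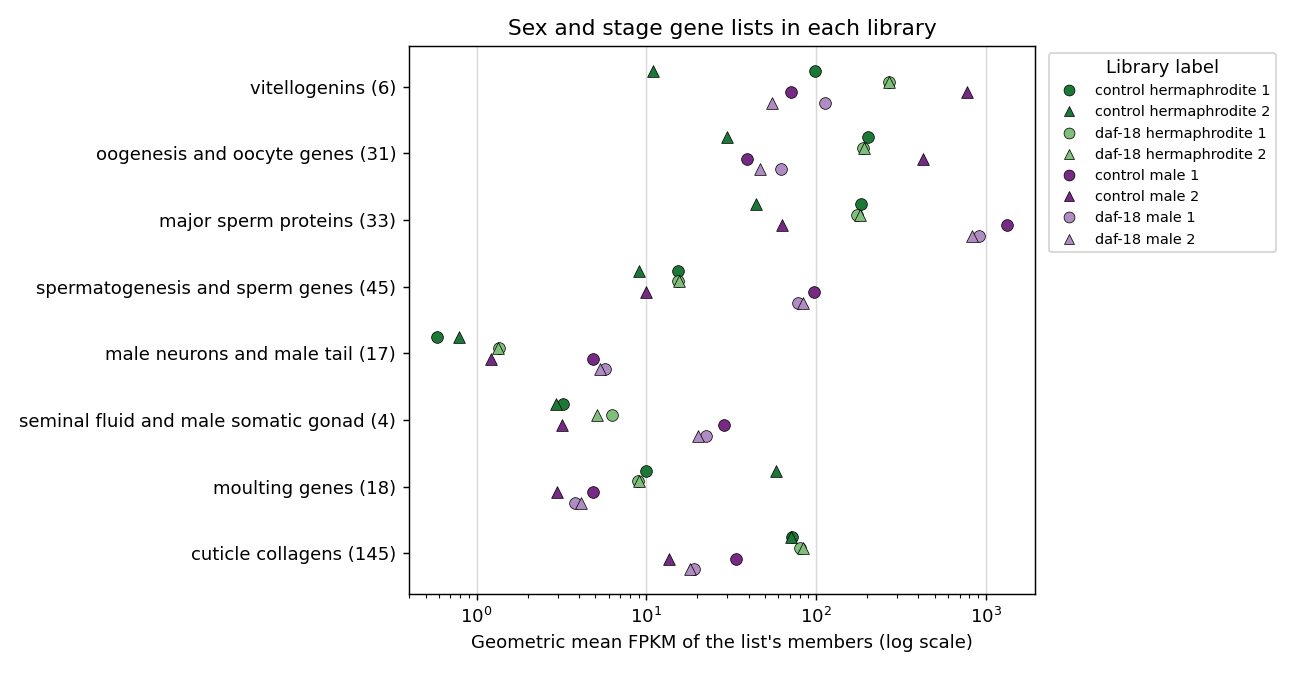
Geometric mean FPKM (log axis) of the members of 8 gene lists in each of the 8 libraries, with circles for library 1 and triangles for library 2 of a group and colours for the groups. The library labelled control male 2 lies with the hermaphrodites for major sperm proteins (63 FPKM against 1331 FPKM in control male 1), and the library labelled control hermaphrodite 2 stands above the other libraries for moulting genes (58.4 FPKM).

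The first comparison asked which transcripts differ between daf-18 mutant and control hermaphrodites. The cuticle collagen genes col-95 (Y41C4A.16, chromosome III, 11703979 to 11705085) and col-101 (K02D7.3, chromosome IV, 325436 to 326671) stood at 537 ± 10.11 and 830.2 ± 12.28 FPKM (SD, n = 2) in the mutants. The libraries labelled control hermaphrodite 1 and 2 held col-95 at 3.85 and 0 FPKM and col-101 at 21.3 and 4.86 FPKM. C33G8.3 (chromosome V, 7007612 to 7008339) stood at 422 ± 14.2 FPKM in the mutants, from 4421 and 4054 reads, and at 1 and 0 reads in the controls. The log2 difference was 7.93 ± 0.78 for col-95 (adjusted p = 0.054) and 6.18 ± 0.58 for col-101 (adjusted p = 0.0525). C33G8.3 had an adjusted p of 0.054, so all 3 missed the threshold. The genes that passed limma's test were 2 of 16038, both 21U-RNA genes, which encode the worm's piRNAs and are listed with a length of 21 bases. 21ur-9213 (chromosome IV, 14053972 to 14053992) had 4 and 5 reads in the mutants and 0 in each control library. 21ur-9014 (chromosome IV, 6027993 to 6028013) had 4 reads in each control and 0 in each mutant hermaphrodite library (both adjusted p = 0.0402). At an unadjusted p under 0.05 there were 781 genes, and limma voom on the recovered reads called 0, with 895 at an unadjusted p under 0.05. The count was 227 without the library labelled control hermaphrodite 1, 1 without control hermaphrodite 2, 184 without control male 1, 187 without control male 2 and 0 without any 1 mutant library, where 206 to 436 genes had an unadjusted p under 0.05.

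No member of any of the 33 lists passed the test over all genes in hermaphrodites. Adjusted over the list alone 6 of 145 cuticle collagens and 1 of 38 hedgehog-related genes rose. They were col-95, col-101, col-98, at 818 ± 53.7 FPKM (SD, n = 2) in the mutants against 82.0 and 163.5 FPKM, col-103, at 578 ± 58.6 FPKM against 98.3 and 170.8 FPKM, col-142, col-143, and grd-3, at 124.9 ± 2.91 FPKM against 28.3 and 23.5 FPKM. By camera with the preset correlation 11 of the 32 lists tested were called. The vitellogenins lay higher as a group, with 6 of 6 members higher and a median log2 difference of 2.92 (adjusted p = 0.000211, and adjusted p = 0.877 with an estimated correlation). Within it vit-3 stood at 142 ± 1.05 FPKM (SD, n = 2) in the mutants and at 24.7 and 4.91 FPKM in the controls. The moulting genes lay lower in 18 of 18 members with a median of -1.57 (adjusted p = 6.27e-06, and adjusted p = 0.877 with an estimated correlation). Among them was lrp-1, a megalin-related receptor needed to shed the cuticle, which stood at 3.15 ± 0.16 FPKM in the mutants against 5.70 and 63.8 FPKM. The oocyte genes (31 of 31 higher, median 1.11, adjusted p = 6.36e-05) and the major sperm proteins (33 of 33 higher, median 0.91, adjusted p = 0.00253) each had an adjusted p = 0.886 with an estimated correlation. The library labelled control hermaphrodite 2 moves with these groups: without it the median was -0.10 for major sperm proteins, -0.08 for oocyte genes and -0.12 for moulting genes, and none of the 3 was called. The vitellogenin median was then 1.60. Without control hermaphrodite 1 the medians were 4.52 for vitellogenins, -3.34 for moulting genes, 2.42 for oocyte genes and 1.802 for major sperm proteins.

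Lists of somatic tissues lay lower in mutant hermaphrodites, as did the mitochondrial genome and lipolysis. The intestine list had a median of -0.69 with 24 of 25 members lower (adjusted p = 6.27e-06), and muscle a median of -0.31 with 19 of 24 lower (adjusted p = 7.44e-05). The pan-neuronal list had a median of -0.54 with 20 of 23 lower (adjusted p = 6.36e-05), and the hermaphrodite somatic gonad, uterus and vulva a median of -0.53 with 17 of 19 lower (adjusted p = 0.000229). The genes of the mitochondrial genome had a median of -0.90 with 11 of 11 lower (adjusted p = 6.0e-06), and lipolysis and fatty acid oxidation a median of -0.32 with 24 of 30 lower (adjusted p = 0.0183). The neuropeptides lay higher, with a median of 0.23 and 51 of 75 members higher (adjusted p = 0.00544). With an estimated correlation the adjusted p of these 7 lists lay between 0.877 and 0.886. Without the library labelled control hermaphrodite 2 the lipolysis list (median -0.06) and the neuropeptides (median 0.07) were no longer called. The lists still called then had medians of -0.33 for the intestine, -0.155 for muscle, -0.225 for pan-neuronal genes, -0.35 for the somatic gonad and -0.22 for the mitochondrial genome. Without control hermaphrodite 1 the medians were -1.15 for the intestine, -0.52 for muscle, -1.575 for the mitochondrial genome, -0.60 for lipolysis and 0.415 for neuropeptides. In the tissue lists, unc-22, which encodes the giant muscle protein twitchin, stood at 7.58 ± 0.195 FPKM in the mutants against 28.3 and 50.7 FPKM, and ges-1, the gut esterase, at 14.2 ± 1.27 FPKM against 25.7 and 54.5 FPKM. The papilin gene mig-6 stood at 58.9 ± 1.70 FPKM against 102.9 and 259.7 FPKM, and unc-104, a kinesin that carries synaptic vesicle precursors, at 4.11 ± 0.189 FPKM against 7.57 and 15 FPKM. None of these 4 passed the gene test (adjusted p = 0.761 for unc-22 and 0.860 for the others).

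The other lists were not called in hermaphrodites. Among insulin-related lists the median log2 difference was -0.02 for DAF-16 class I genes (adjusted p = 0.589), -0.90 for DAF-16 class II genes (adjusted p = 0.232), -0.23 for insulin/PI3K pathway components (adjusted p = 0.155) and 0.30 for insulin-like peptides (adjusted p = 0.0948). Among germline lists it was 0.33 for sperm genes (adjusted p = 0.165), 0.20 for general germline genes (adjusted p = 0.232), 0.32 for cell cycle genes (adjusted p = 0.102) and 0.16 for early embryonic genes (adjusted p = 0.559). Cuticle collagens had -0.30 (adjusted p = 0.528), hedgehog-related genes -0.34 (adjusted p = 0.623) and fatty acid synthesis -0.23 (adjusted p = 0.165). Innate immune genes had -0.18 (adjusted p = 0.343), heat shock genes 0.05 (adjusted p = 0.328) and antioxidant and detoxification genes -0.22 (adjusted p = 0.0688). Male neurons and the male tail had 0.47 (adjusted p = 0.102) and sex determination genes -0.47 (adjusted p = 0.201). The list of coelomocytes, excretory system and pharyngeal gland had -0.30 (adjusted p = 0.221). Cytosolic ribosomal proteins had 0.05 (adjusted p = 0.134), the nuclear-encoded respiratory chain 0.04 (adjusted p = 0.869), histones -0.08 (adjusted p = 0.408) and ribosomal RNA -0.05 (adjusted p = 0.532). The 4 seminal fluid genes, too few to test, had a median of 0.45. These adjusted p-values are from limma's camera.

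Without the doubted control libraries, 702 of 15641 genes passed in hermaphrodites, 445 higher and 257 lower in the mutants, against 1 control library. Both collagens rose, by 6.80 ± 0.13 for col-95 and 5.22 ± 0.10 for col-101 on the log2 scale (both adjusted p = 7.54e-05), as did C33G8.3 (adjusted p = 0.00174). The next rises were in genes with high levels in males. The insulin-like peptide gene ins-31 (chromosome II, 3127041 to 3127811) stood at 44.7 ± 0.346 FPKM (SD, n = 2) in mutant hermaphrodites, at 2 reads in each library labelled control hermaphrodite, and at 744.7 ± 50.3 FPKM in mutant males. The C-type lectin gene clec-197 stood at 42.8 ± 3.04 FPKM in mutant hermaphrodites against 1 and 7 reads in the controls and 872 ± 208 FPKM in mutant males. K12H6.9 stood at 54.4 ± 0.794 FPKM against 2 and 0 reads and 798 ± 50.99 FPKM. The adjusted p was 7.54e-05 for ins-31 and K12H6.9 and 0.000520 for clec-197, and K12H6.4, F09C6.10, C05B5.11 and Y110A2AL.7 followed. Of the 445 rises, 287 (64.5%) were at least 4-fold higher in the library labelled control male 1 than in control hermaphrodite 2, which plays no part in this fit. The same held for 18 of the 257 falls (7.004%) and 2172 (13.9%) of all genes tested. Over the alternatives the adjusted p of the genes named in this comparison ran from 7.54e-05 to 1.

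In the same fit, M106.2 fell by 2.50 ± 0.12 on the log2 scale (adjusted p = 0.000840), standing at 7.04 ± 0.0167 FPKM in the mutants and at 44.6 FPKM in control hermaphrodite 1. F09E5.9 (adjusted p = 0.0161) and K07B1.8 (adjusted p = 0.0457) followed, and the other 7 of the 10 largest falls were 21U-RNA genes with 0 reads in both mutant libraries. Of 24 muscle genes 6 fell and none rose, and 9 fell adjusted over the list alone. They include the pharyngeal myosin genes myo-1, which fell by 1.51 ± 0.11 (adjusted p = 0.00304), and myo-2, which fell by 1.48 ± 0.14 (adjusted p = 0.00809). Of 143 cuticle collagens 14 rose and 11 fell, 24 and 27 adjusted over the list alone, and the list was not called (adjusted p = 0.922). Among male genes, cwp-1, expressed in male sensory neurons, stood at 3.94 ± 0.413 FPKM in mutant hermaphrodites, at 0 and 0.355 FPKM in the libraries labelled control hermaphrodite 1 and 2, and at 104.3 and 95.74 FPKM in the mutant male libraries (adjusted p = 0.00209 in hermaphrodites). Of 22 DAF-16 class I genes 1 rose and 2 fell, and 2 and 5 did so adjusted over the list alone, with no call of the list (adjusted p = 0.922). The 1 that rose was sod-3, a mitochondrial superoxide dismutase and a known target of DAF-16, by 1.07 ± 0.15 (adjusted p = 0.0261). Of 82 cytosolic ribosomal proteins 80 lay higher, with a median of 0.27 (camera adjusted p = 3.23e-07, and adjusted p = 0.731 with an estimated correlation), and no member passed. Histones, a marker of RNA quality, lay higher in 29 of 38 members (median 0.43, camera adjusted p = 0.00248, and adjusted p = 0.516 with an estimated correlation).

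**Figure D2:**
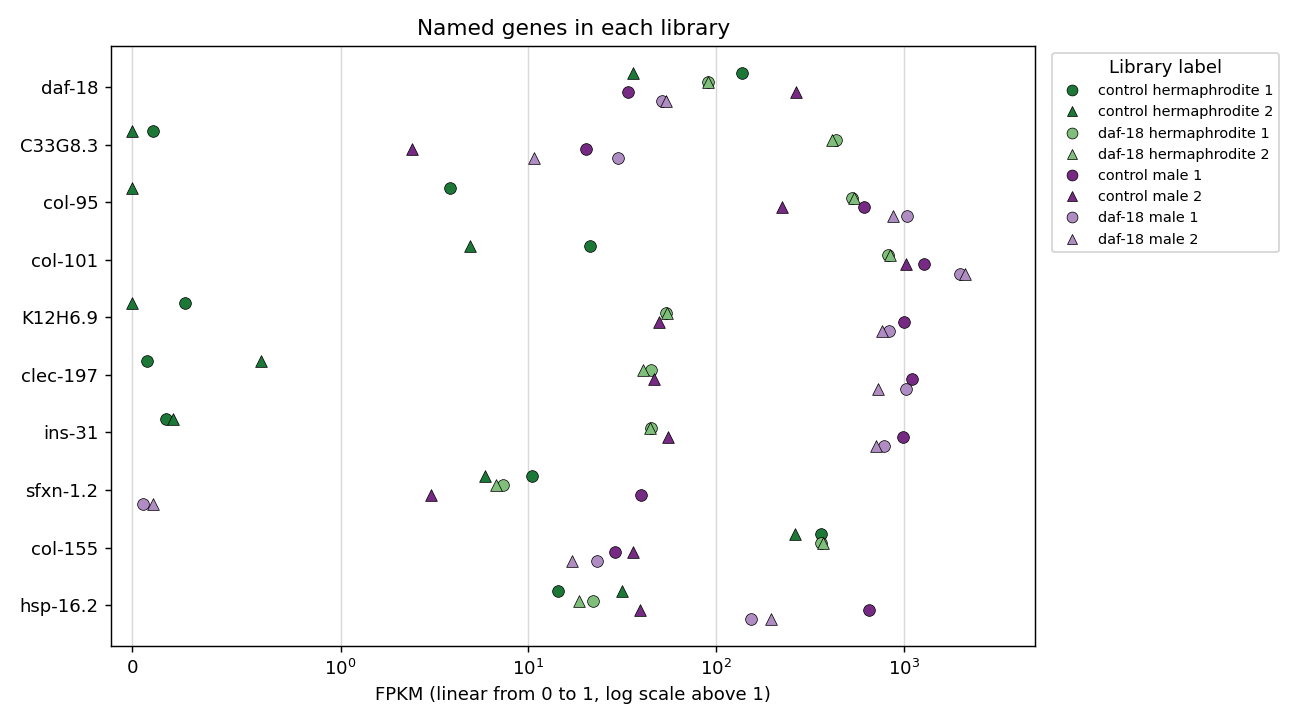
FPKM of 10 genes in each of the 8 libraries, on an axis that is linear from 0 to 1 and logarithmic above 1, with circles for library 1 and triangles for library 2 of a group. col-95 and col-101 stand at 537 and 830.2 FPKM on average in mutant hermaphrodites and at 21.3 FPKM or less in both libraries labelled control hermaphrodite, while daf-18 is detected in every library.

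The second comparison asked which transcripts differ between daf-18 mutant and control males. Among germline markers, the sperm genes had a geometric mean of 77.9 and 84.1 FPKM in the mutant males, 97.0 FPKM in control male 1 and 9.996 FPKM in the library labelled control male 2. The oocyte genes stood at 62.1 and 46.7 FPKM in the mutants, at 38.98 FPKM in control male 1 and at 428 FPKM in the library labelled control male 2. The sperm gene fer-1, which encodes a ferlin needed for membrane fusion in sperm, stood at 24.3 ± 4.75 FPKM (SD, n = 2) in the mutants and at 18.3 and 2.58 FPKM in the libraries labelled control male 1 and 2. By limma's test 0 of 16038 genes passed, with 233 at an unadjusted p under 0.05, and limma voom also called 0, with 171 at an unadjusted p under 0.05. The count was 5584 without control male 1, where the only control is the library labelled control male 2. It was 0 without any other library, where 90 to 393 genes had an unadjusted p under 0.05.

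By camera 14 of 32 lists were called in males, each with an adjusted p = 0.862 with an estimated correlation, and no member of any list passed, over all genes or adjusted over the list alone. The major sperm proteins (33 of 33 higher, median 1.53, adjusted p = 5.82e-07), sperm genes (43 of 45 higher, median 1.46, adjusted p = 1.55e-09), male neurons and the male tail (16 of 17 higher, median 0.78, adjusted p = 7.39e-06) and neuropeptides (69 of 75 higher, median 0.64, adjusted p = 3.67e-09) lay higher. The pan-neuronal genes (median 0.46, adjusted p = 0.00121), DAF-16 class I genes (median 0.60, adjusted p = 0.00275) and innate immune genes (median 0.52, adjusted p = 0.0149) lay higher too. The oocyte genes (31 of 31 lower, median -1.25, adjusted p = 5.88e-06), vitellogenins (median -1.57, adjusted p = 0.0228), general germline genes (median -0.53, adjusted p = 7.30e-05) and cell cycle genes (median -0.86, adjusted p = 7.39e-06) lay lower. So did sex determination genes (median -0.50, adjusted p = 0.00365), cuticle collagens (median -0.17, adjusted p = 0.0233) and cytosolic ribosomal proteins (median -0.44, adjusted p = 8.48e-26). The library labelled control male 2 decides most of these directions. Without it the median was -0.64 for major sperm proteins, -0.26 for sperm genes, 0.44 for oocyte genes, 0.28 for general germline genes and 0.26 for cell cycle genes. It was 0.22 for sex determination genes and -0.31 for innate immune genes. DAF-16 class I genes (-0.09), vitellogenins (0.16) and neuropeptides (0.03) were no longer called. Still called in the same direction were male neurons and the male tail at 0.178, pan-neuronal genes at 0.18, collagens at -0.94 and cytosolic ribosomal proteins. Without control hermaphrodite 2 as well the list of male neurons was not called. Without control male 1 the medians were 3.76 for major sperm proteins, 3.18 for sperm genes, 1.665 for male neurons, 1.205 for neuropeptides, 0.74 for pan-neuronal genes, 1.54 for DAF-16 class I genes and 1.25 for innate immune genes. They were -3.04 for oocyte genes, -3.27 for vitellogenins, -1.39 for general germline genes, -2.24 for cell cycle genes and -1.19 for sex determination genes. Without control male 1 the collagen median was 0.53, without mutant male library 2 the vitellogenin median was -1.03, and without mutant male library 1 the innate immune median was 0.33. These 3 calls ended.

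Without the doubted control libraries, 129 of 15641 genes passed in males, 13 higher and 116 lower, against 1 control library. Cuticle collagens made up 53 of the falls: of 143 members 53 fell and none rose, and 89 fell and 3 rose adjusted over the list alone. col-63 stood at 13.8 ± 1.22 FPKM (SD, n = 2) in the mutants against 59.3 FPKM in control male 1. It fell by 2.02 ± 0.12 on the log2 scale, and col-71 fell by 1.65 ± 0.10 (both adjusted p = 0.0115). The list median was -0.94 (camera adjusted p = 8.89e-35, and adjusted p = 0.370 with an estimated correlation). Markers of RNA quality and of sperm lay lower in the same fit. Histones had a median of -0.256 (27 of 38 lower, camera adjusted p = 0.0383), ribosomal RNA -0.55 (6 of 7, adjusted p = 0.0497), the mitochondrial genome -0.52 (11 of 11, adjusted p = 3.48e-06) and major sperm proteins -0.64 (32 of 33, adjusted p = 3.21e-19). Adjusted over the list alone 28 major sperm proteins, 9 mitochondrial genes, 1 ribosomal RNA gene and no histone fell, and with an estimated correlation the adjusted p of these 4 lists ran from 0.370 to 0.556. The library labelled control male 2, left out here, held col-63 at 6.998 FPKM, below the mutants. Of the heat shock genes 2 of 31 fell, and 6 adjusted over the list alone, among them the small heat shock protein gene hsp-16.2, which fell by 1.90 ± 0.18 (adjusted p = 0.0203). It stood at 649 FPKM in control male 1, at 174 ± 29.6 FPKM in the mutants and at 39.2 FPKM in the library labelled control male 2. The sideroflexin gene sfxn-1.2 (F37H8.4, chromosome II, 11186028 to 11188080) had 1 and 2 reads in the mutant males, 691 reads in control male 1 and 47 reads in control male 2 (adjusted p = 0.00716). The other large falls included the C-type lectin gene clec-2 (adjusted p = 0.0237), nspa-7 (adjusted p = 0.0441), R09E12.9 (adjusted p = 0.0209) and the RNase P RNA gene rpr-1 (adjusted p = 0.0242).

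Outside the 21U-RNA genes, the rises in that fit included Y71F9AL.4, at 93.5 ± 10.7 FPKM in the mutant males against 18.3 FPKM in control male 1 and 11.1 FPKM in control male 2 (log2 difference 2.29 ± 0.16, adjusted p = 0.0115). F15E11.15 stood at 330.1 ± 1.97 FPKM against 142 and 62.3 FPKM (1.21 ± 0.09, adjusted p = 0.0126). The adenylyl cyclase-associated protein gene cas-1 stood at 87.5 ± 11.9 FPKM against 26.6 and 58.5 FPKM (adjusted p = 0.0163), and acp-6 at 570.8 ± 10.8 FPKM against 279 and 549 FPKM (adjusted p = 0.0182). The Notch receptor gene glp-1, which maintains germline stem cells, rose by 1.21 ± 0.14 (adjusted p = 0.0371), but stood at 83.4 FPKM in the library labelled control male 2, above the 11.5 ± 1.21 FPKM of the mutants. T04B8.5 and nhl-3 also rose (adjusted p = 0.0115 and 0.0213), with 0 and 3 reads in control male 1, but 639 and 298 reads in control male 2. Over the alternatives the adjusted p of the genes named in this comparison ran from 0.00295 to 1.

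The third comparison tested whether the change with genotype differed between males and hermaphrodites. Vitellogenins and oocyte genes, higher in mutant hermaphrodites and lower in mutant males, had a median interaction of -4.55 and -2.41 on the log2 scale, with 6 of 6 and 31 of 31 members below 0. Moulting genes had a median of 1.31 with 18 of 18 members above 0, pan-neuronal genes a median of 0.98 with 21 of 23 above 0, and the intestine a median of 0.97 with 24 of 25 above 0. egl-3, a proprotein convertase that processes neuropeptides, stood at 40.8 ± 1.19 FPKM (SD, n = 2) in mutant hermaphrodites against 68.7 and 102 FPKM in their controls, and at 77.2 ± 11.7 FPKM in mutant males against 53.6 and 39.02 FPKM (interaction 1.75 ± 0.55, adjusted p = 0.723). By limma 0 of 16038 genes passed, with 575 at an unadjusted p under 0.05, and limma voom called 0, with 568 at an unadjusted p under 0.05. The count was 16 without control hermaphrodite 1, 3243 without control male 1, 58 without control male 2 and 0 without any other library, where 141 to 460 genes had an unadjusted p under 0.05. Camera called 15 lists, each with an adjusted p = 0.846 with an estimated correlation. The oocyte call ended without control male 2 (median -0.75), and without both doubted control libraries oocyte genes were called in the other direction (0.66). The moulting call ended without control hermaphrodite 2 (0.07) or control male 1 (1.83), and its median was 3.03 without control hermaphrodite 1. Oocyte genes had -1.05 without control hermaphrodite 2 and -4.11 without control male 1, and vitellogenins -2.865 without control male 2. The intestine had 1.47 without control hermaphrodite 1, 0.61 without control hermaphrodite 2, 0.635 without control male 2 and 0.05 without both doubted libraries. Adjusted over the list alone 3 collagens passed and no other member did.

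Without the doubted control libraries 878 genes had an interaction, 344 above 0 and 534 below. Of 143 cuticle collagens 56 were below 0 and none above, 94 adjusted over the list alone, with a median of -0.95 (camera adjusted p = 6.08e-24, and adjusted p = 0.376 with an estimated correlation). Histones (34 of 38, median -0.64, camera adjusted p = 0.000402), ribosomal RNA (7 of 7, median -0.63, adjusted p = 0.0487) and cytosolic ribosomal proteins (82 of 82, median -0.605, adjusted p = 6.33e-14) lay below 0 in the same fit, with adjusted p = 0.376, 0.599 and 0.529 with an estimated correlation. Oocyte genes lay above 0 in 25 of 31 members, 8 of which passed and 14 adjusted over the list alone (median 0.66, camera adjusted p = 3.56e-06, and adjusted p = 0.480 with an estimated correlation). Vitellogenins lay below 0 in 6 of 6, with 3 passing over the list alone (median -1.28, adjusted p = 0.0479, and adjusted p = 0.599 with an estimated correlation). col-95 had an interaction of -6.15 ± 0.18 (adjusted p = 0.000627), standing at 954 ± 112 FPKM in mutant males and at 609.6 and 223 FPKM in the control male libraries, and C33G8.3, at 20.4 ± 13.7 FPKM in mutant males and 20.3 and 2.40 FPKM in the control males, had an adjusted p of 0.00764. ins-31, K12H6.9 and clec-197 followed (adjusted p = 0.000596, 0.000596 and 0.00180). Outside the 21U-RNA genes, the largest above 0 were K07B1.8 (3.87 ± 0.50, adjusted p = 0.0219) and T04B8.5 (adjusted p = 0.0142), the latter with 0 reads in control male 1. Over the alternatives the adjusted p of the genes named here ran from 0.000596 to 0.955.

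The fourth comparison, males against hermaphrodites among the mutants, used 4 libraries that were close to each other within each sex. Sperm genes were higher in mutant males: the list had a geometric mean of 77.9 and 84.1 FPKM in males and of 15.4 and 15.7 FPKM in hermaphrodites, and the sperm phosphatase gene gsp-3 stood at 734 ± 10.7 against 131 ± 1.17 FPKM (SD, n = 2). Oocyte genes were lower in males, and egg-5, a pseudophosphatase of the oocyte-to-embryo transition, stood at 17.7 and 15.1 FPKM against 67.3 and 65.5 FPKM. The collagen gene col-155 (F55C10.3, chromosome V, 11388890 to 11389875) stood at 20.1 ± 4.38 FPKM in males and 364 ± 6.45 FPKM in hermaphrodites. In the fit over all 8 libraries 3 genes passed (each adjusted p = 0.0489). They were col-155, which fell by 4.13 ± 0.36 on the log2 scale in males, 21ur-9213, and 21ur-15070 with 4 and 3 reads in mutant males and 0 elsewhere. In all, 2873 genes had an unadjusted p under 0.05. That fit shares the spread of the control libraries. The count was 39 without control hermaphrodite 1, 38 without control hermaphrodite 2, 3597 without control male 1, 3572 without control male 2, and 0 without any 1 mutant library, where 888 to 1074 genes had an unadjusted p under 0.05. limma voom called 0, with 2885 at an unadjusted p under 0.05.

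Fitted on the 4 mutant libraries alone, 9701 of 15164 genes passed, 4988 higher and 4713 lower in males, and the fit of all groups without the doubted control libraries called 9624 of 15641. Of the genes tested in both, 9540 were called in the same direction by each. Both fits take this comparison and its spread from the same 4 mutant libraries, so their agreement is no separate support. All 33 major sperm proteins rose in males (median 2.32), as did 43 of 45 sperm genes (median 2.48), with 1 falling, and all 31 oocyte genes fell (median -1.79), as did the 6 vitellogenins (median -1.805). Among somatic male genes, 13 of 16 male neuron and male tail genes rose and 1 fell. The rises included cwp-1, mab-3, which encodes a transcription factor of male development at 43.3 ± 0.428 FPKM in males against 7.14 ± 1.41 FPKM, and pkd-2, the polycystin of male sensory neurons at 6.22 ± 0.814 against 0.800 ± 0.0293 FPKM. All 4 seminal fluid genes rose, including the seminal fluid protease gene try-5 at 17.1 ± 1.17 against 2.02 ± 0.625 FPKM. Of 142 cuticle collagens 112 fell and 21 rose, and of 17 moulting genes 12 fell and 3 rose. Of 22 DAF-16 class I genes 18 rose and 2 fell, including the metallothionein gene mtl-2 at 55.7 ± 7.12 against 10.3 ± 0.201 FPKM. Of 40 innate immune genes 27 rose and 4 fell, of 75 neuropeptides 51 rose and 6 fell, and of 82 cytosolic ribosomal proteins 79 fell and 1 rose.

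Over all 8 libraries camera called 18 lists in this comparison, with an adjusted p from 0.742 to 0.815 with an estimated correlation. Without control male 1 or control male 2 the calls ended for DAF-16 class II genes (1.945 and 1.858), muscle (-0.164 in both), the somatic gonad (-0.54 in both), moulting genes (-1.26 in both), pan-neuronal genes (0.42 in both) and vitellogenins (-1.805 in both). They ended without mutant hermaphrodite library 1 for pan-neuronal genes (0.42) and without mutant hermaphrodite library 2 for muscle (-0.132), the somatic gonad (-0.39), pan-neuronal genes (0.42) and vitellogenins (-1.807). They ended without mutant male library 1 for the somatic gonad (-0.47) and without mutant male library 2 for muscle (-0.167), pan-neuronal genes (0.41) and vitellogenins (-1.28). Fitted on the mutant libraries, camera called 15 of 32 lists and fry 25, and with an estimated correlation the smallest adjusted p was 0.352. Adjusted over the list alone, the counts were 112 falls and 22 rises for collagens, 28 rises for innate immune genes, 52 rises and 7 falls for neuropeptides and 80 falls for ribosomal proteins, and those of the other lists named above were the same as over all genes. The camera adjusted p was 4.69e-14 for major sperm proteins and for sperm genes, 9.37e-12 for oocyte genes and 1.38e-17 for collagens. Among single genes, C08E8.11 stood at 88.2 ± 13.9 FPKM in mutant males and had 1 read in each mutant hermaphrodite library, and clec-134 at 76.0 ± 5.52 FPKM with 1 and 2 reads (both adjusted p = 7.22e-06). F26D10.13 stood at 555 ± 36.95 FPKM against 6.26 ± 0.603 FPKM (6.26 ± 0.10 on the log2 scale, adjusted p = 7.22e-06), and clec-94 and T22G5.1 followed. The largest falls in males were in Y47D7A.15, at 40.6 ± 4.47 against 1611 ± 152 FPKM (-5.28 ± 0.12, adjusted p = 7.22e-06), nspb-6, nspb-1, T06E4.8 and col-137. Over the alternatives the adjusted p of the genes named in this comparison ran from 5.76e-07 to 0.843.

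The fifth comparison, between the sexes in controls, set the libraries labelled control male 1 and 2 against control hermaphrodite 1 and 2. Control male 2 held few male transcripts, so calls here need not reflect sex. The collagen genes col-95 and col-101 rose in males, by 7.39 ± 0.78 (adjusted p = 0.0371) and 6.64 ± 0.58 (adjusted p = 0.0302) on the log2 scale, with col-101 at 1270 and 1026 FPKM in males against 21.3 and 4.86 FPKM in hermaphrodites. The hedgehog-related gene grd-3 rose by 2.95 ± 0.31 (adjusted p = 0.0371), from 28.3 and 23.5 FPKM to 196.9 and 216 FPKM. F41E6.15 and scl-24 rose too (adjusted p = 0.0371 and 0.0458). In mutants col-95, col-101, grd-3 and F41E6.15 differed less by sex. The falls in males included col-162, from 875 and 467 FPKM to 51.5 and 16.17 FPKM (adjusted p = 0.0431), Y47G6A.15, from 348 and 919 FPKM to 25.6 and 10.4 FPKM (adjusted p = 0.0399), Y51H7C.13 (adjusted p = 0.0302) and F10D11.6 (adjusted p = 0.0436). By limma 78 of 16038 genes passed, 10 higher and 68 lower in males, 65 of them protein-coding, with 2267 at an unadjusted p under 0.05. The split by direction depends on the settings: 151 were higher and 140 lower with a pseudocount of 0.1, 36 and 195 with quantile normalization, 213 and 266 without control male 1, and 2717 and 1166 without control male 2, while 633 of 734 were lower without control hermaphrodite 1. The 21U-RNA genes 21ur-6244, with 5 and 3 reads in the male libraries alone, and 21ur-8543 were among them. The count was 734 without control hermaphrodite 1, 2 without control hermaphrodite 2, 479 without control male 1, 3883 without control male 2 and 0 without any 1 mutant library, where 1576 to 1624 genes had an unadjusted p under 0.05. limma voom called 0, with 2236 at an unadjusted p under 0.05.

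Camera called 16 lists in the sex comparison of controls, with an adjusted p from 0.413 to 0.858 with an estimated correlation. Cuticle collagens lay lower in males (110 of 145 lower, median -2.56, adjusted p = 5.52e-20), with 5 falling and 3 rising, and 89 falling and 18 rising adjusted over the list alone. Moulting genes lay lower (17 of 18, median -2.50, adjusted p = 2.06e-09), with 9 falls adjusted over the list alone, and the moulting peroxidase gene mlt-7 stood at 6.47 and 5.69 FPKM in males against 36.6 and 26.1 FPKM (adjusted p = 0.068). Muscle genes lay lower too (21 of 24, median -0.90, adjusted p = 4.88e-09), with 13 falls adjusted over the list alone. So did hedgehog-related genes (median -1.82, adjusted p = 2.65e-07), the hermaphrodite somatic gonad (median -1.11, adjusted p = 3.40e-06), and the mitochondrial genome (median -0.91, adjusted p = 3.64e-05). Further lower lists were pan-neuronal genes (median -0.49, adjusted p = 0.000932), coelomocytes, excretory system and pharyngeal gland (median -0.51, adjusted p = 0.00158), the intestine (median -0.27, adjusted p = 0.00264) and ribosomal proteins (median -0.11, adjusted p = 0.0387). Major sperm proteins (median 1.68, adjusted p = 0.000738), sperm genes (median 1.26, adjusted p = 5.72e-05), vitellogenins (median 2.68, adjusted p = 0.0143), male neurons and the male tail (median 0.97, adjusted p = 0.0106), heat shock genes (median 0.66, adjusted p = 0.00259) and histones (median 0.58, adjusted p = 0.008) lay higher. Oocyte genes were higher in males in 29 of 31 members but not called (median 0.705, adjusted p = 0.226). The higher vitellogenins rest on the doubted control libraries, with a median of 1.36 without control hermaphrodite 2 and 0.98 without control male 2, neither called. Without control male 1 the median was -0.55 for major sperm proteins, -0.44 for sperm genes, 0.22 for male neurons and 0.14 for histones, without control hermaphrodite 2 it was 0.13 for ribosomal proteins and 0.05 for the intestine, and without control hermaphrodite 1 it was 0.34 for histones. Further calls ended without control hermaphrodite 2 for major sperm proteins (0.71), without control hermaphrodite 1 for heat shock genes (0.48) and male neurons (0.81), and without control male 1 for ribosomal proteins (-0.02). Without control male 2 they ended for pan-neuronal genes (-0.35), the intestine (0.04), the coelomocyte list (-0.74) and the mitochondrial genome (-0.58). Calls that stood moved too. Without control hermaphrodite 1 the median was -4.66 for moulting genes, -1.54 for the mitochondrial genome, -1.178 for the coelomocyte list and -0.83 for the intestine. It was -0.32 for ribosomal proteins, 2.59 for major sperm proteins and 4.17 for vitellogenins. Without control hermaphrodite 2 it was -1.201 for moulting genes, -1.15 for hedgehog-related genes, -0.285 for the mitochondrial genome and -0.24 for the coelomocyte list. Without control male 1 it was -0.95 for the intestine, -0.82 for pan-neuronal genes and 4.58 for vitellogenins. Without control male 2 it was 3.84 for major sperm proteins, 2.95 for sperm genes, 1.94 for male neurons, 0.915 for histones and -0.22 for ribosomal proteins.

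Without the doubted control libraries, 8897 of 15641 genes differed between control male 1 and control hermaphrodite 1, 4741 higher and 4156 lower in the male library, with the spread taken from the mutant libraries. The major sperm proteins rose in 33 of 33 members (median 2.85), sperm genes in 43 of 45 (median 2.66) and male neuron and male tail genes in 11 of 17, with 2 falling, and oocyte genes fell in 30 of 31 (median -2.55). The vitellogenin median was -0.39, with 0 rising and 2 falling, and the list was not called (adjusted p = 0.489). myo-1, which encodes a pharyngeal myosin, fell by 2.84 ± 0.13 (adjusted p = 7.55e-05), and col-95 rose by 6.98 ± 0.15 (adjusted p = 1.85e-05). Of the 78 genes called with all libraries 66 were tested in this fit, and all 66 were called in the same direction. Over the alternatives the adjusted p of the genes named in this comparison ran from 1.71e-05 to 1.

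The changes with genotype in the 2 sexes were compared gene by gene, and no control library was shared between them. With all libraries 0 genes were called in both, since limma called 2 in hermaphrodites and 0 in males. Across genes the log2 differences correlated at a Pearson r of -0.03 and a Spearman rho of -0.14. Without the doubted control libraries 22 genes fell in both sexes, against 1.91 for independent lists, 1 rose in both, against 0.370, and 13 went opposite ways, against 3.51. Both comparisons use the same residual variance, so calls in them are not independent. The correlation across genes was then r = -0.13 and rho = -0.22. Among genes called with at least a 2-fold difference, 8 fell and 1 rose in both, against 0.732 and 0.223 for independent lists, and 10 went opposite ways, against 2.48.

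**Figure D3:**
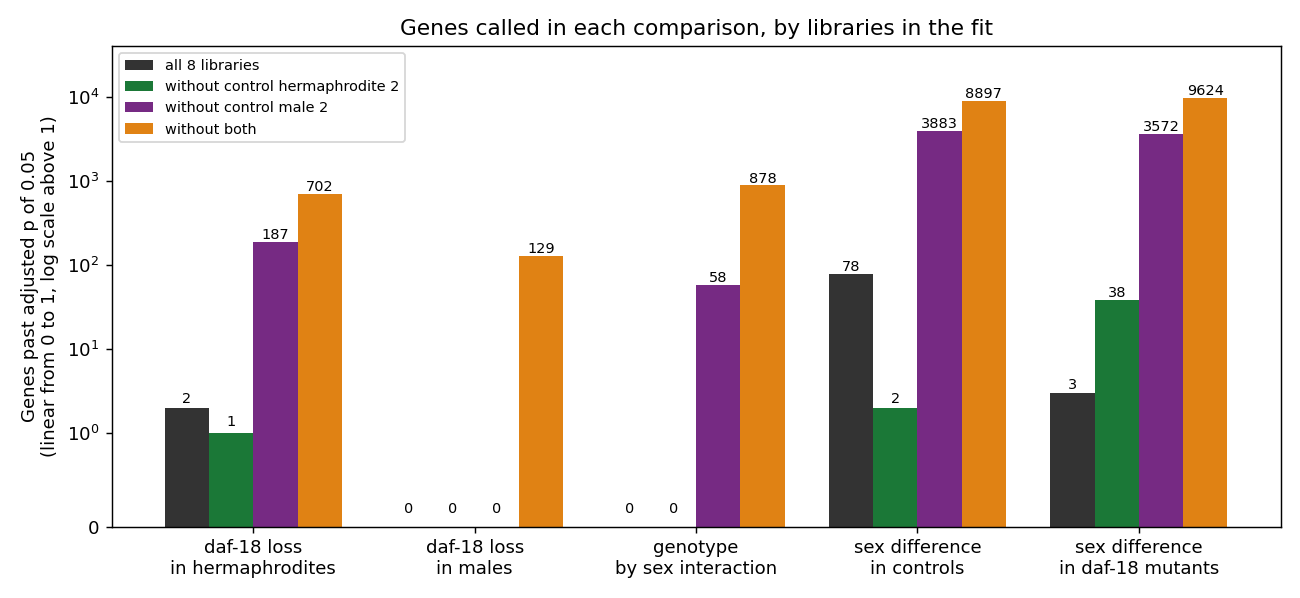
Number of genes past an adjusted p of 0.05 in each of the 5 comparisons (bars, on an axis that is linear to 1 and logarithmic above), with all 8 libraries, without the library labelled control hermaphrodite 2, without the library labelled control male 2, and without both. The hermaphrodite comparison calls 2, 1, 187 and 702 genes and the male comparison 0, 0, 0 and 129.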

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

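The tests of all 8 explanations here were chosen after the result was seen, and the list tests of the interaction in advance. The change with genotype differed between the sexes in 15 gene lists by camera with the preset correlation, each with an adjusted p = 0.846 with an estimated correlation. Medians of the log2 interaction above 0 mean that the change was higher in males. Below 0 lay the vitellogenins (median -4.55, 6 of 6 members, adjusted p = 9.45e-05), oocyte genes (-2.41, 31 of 31, adjusted p = 1.90e-08) and cell cycle genes (-1.202, 28 of 28, adjusted p = 5.46e-05). So did general germline genes (-0.62, 29 of 33, adjusted p = 0.000895) and cytosolic ribosomal proteins (-0.47, 78 of 82, adjusted p = 2.75e-15). Above 0 lay moulting genes (1.31, 18 of 18, adjusted p = 0.00121), sperm genes (1.098, 41 of 45, adjusted p = 0.00558), pan-neuronal genes (0.98, 21 of 23, adjusted p = 2.88e-06) and the intestine (0.97, 24 of 25, adjusted p = 4.20e-05). Further lists above 0 were the hermaphrodite somatic gonad (0.82, 14 of 19, adjusted p = 0.0191), the mitochondrial genome (0.64, 11 of 11, adjusted p = 0.0189) and DAF-16 class I genes (0.63, 18 of 22, adjusted p = 0.0326). Muscle (0.47, 22 of 24, adjusted p = 9.58e-05) and innate immune genes (0.40, 32 of 43, adjusted p = 0.0326) lay above 0 too. Cuticle collagens were called lower (adjusted p = 0.0326), with a mean of -0.41 but a median of 0.07.

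Leaving out 1 library ended or turned 10 of these 15 calls. Those of vitellogenins, muscle, the intestine, ribosomal proteins and pan-neuronal genes stood. Without both doubted control libraries, the median was 0.05 for the intestine and 0.06 for muscle. Without the library labelled control male 2 the median was -0.75 for oocyte genes, 0.09 for general germline genes, -0.01 for cell cycle genes, -0.27 for DAF-16 class I genes, -0.26 for innate immune genes and 0.32 for the mitochondrial genome, none of them called, and -0.55 for sperm genes, called in the other direction. Calls that stood were then at -2.87 for vitellogenins, 0.12 for muscle, -0.71 for collagens and 0.64 for the intestine. Without the library labelled control hermaphrodite 2 the calls ended for moulting genes (0.07), the mitochondrial genome (0.00), innate immune genes (0.09), general germline genes (-0.37), cell cycle genes (-0.67) and the somatic gonad (0.60), and the medians were -1.05 for oocyte genes, 0.61 for the intestine and -0.24 for collagens. Without control male 1 they ended for moulting genes (1.83), the somatic gonad (0.71), collagens (0.85) and the mitochondrial genome (0.93). The medians were then -4.11 for oocyte genes, 2.90 for sperm genes, 1.88 for DAF-16 class I genes, 1.32 for innate immune genes, -2.55 for cell cycle genes, -1.53 for general germline genes and 0.87 for muscle. Without control hermaphrodite 1 they ended for sperm genes (0.72) and DAF-16 class I genes (1.011). The medians were then 3.03 for moulting genes, 1.32 for the mitochondrial genome, 1.47 for the intestine, -1.81 for cell cycle genes, 0.62 for innate immune genes, 0.20 for collagens and -0.25 for ribosomal proteins, which stood at -0.71 without control hermaphrodite 2. Of the mutant libraries, mutant hermaphrodite library 1 ended the call of DAF-16 class I genes (0.56), mutant hermaphrodite library 2 that of the mitochondrial genome (0.51) and mutant male library 1 that of innate immune genes (0.44), and without mutant male library 2 the innate immune median was 0.66. The collagen median was -0.02 and 0.13 without mutant hermaphrodite library 1 and 2, and -0.03 and 0.12 without mutant male library 1 and 2.

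In 10 of the 72 genes named for the genotype comparisons both mutant libraries lay above both controls in 1 sex and below both in the other. Many of these genes were named for small p-values in the same libraries, so no share by chance applies to them. Among all 16038 tested genes 1699 (10.6%) did so, and 593 (3.70%) had both mutant libraries on the same side of the controls in both sexes. The log2 interaction was 3.82 for F15E11.15, 2.79 for fer-1, 1.86 for ges-1, 1.75 for egl-3, 1.70 for myo-2, 1.63 for unc-104, 1.60 for unc-13, 1.59 for spe-9, 1.19 for flp-16 and 1.11 for ech-1. None passed limma's test of the interaction (each adjusted p = 0.723).

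High levels of oocyte and yolk transcripts and low levels of male transcripts marked the library labelled control male 2. An exchange of labels was tested for the 2 control hermaphrodite libraries only, not for mutant libraries or labelled samples outside the 8 libraries. With these 2 it is argued against, over 174 male-biased genes chosen in the mutant libraries alone. Neither control hermaphrodite library held more than a median of 0.0923% of the control male 1 level (quartiles 0 to 0.409%). Hermaphrodites of the same stage as control hermaphrodite 1 are argued against too, since over 118 hermaphrodite-biased genes, also chosen in the mutant libraries and 41 of them collagens, this library held a median of 2.48% of the level there (1.68 to 3.54%). A sample of mostly hermaphrodites of another stage with few males stays open: the male-biased genes stood at a median of 6.22% of the control male 1 level (4.93 to 8.54%), and the oocyte genes above both control hermaphrodite libraries. As a hypothesis this library may hold hermaphrodites with more oocytes, and no biological explanation within males was tested.

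The library labelled control hermaphrodite 2 stood apart from the other 3 hermaphrodite libraries. Lower depth is argued against, with 18121950 reads against 17067648 to 17535896 in the other 3. Younger, still moulting animals stay open as a hypothesis: 16 of 18 moulting genes were higher than in the other 3 libraries and 31 of 31 oocyte genes lower. A difference in age between samples is not in the labels, so it may lie in the synchronization or in the sample, and neither could be tested here.

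Male-restricted transcripts, 198 genes chosen to be high in males and at 1 FPKM or less in both libraries labelled control hermaphrodite, stood in the mutant hermaphrodites at a median of 5.93% of the mutant male level (quartiles 4.37 to 8.29%) and in the library labelled control male 2 at 7.01%. A small share of males, or carry-over from the mutant male libraries, is a candidate explanation and needs such a nearly constant share. For 4 of 153 genes reads were more than 4 times fewer than expected. They were C08E8.11 (48.4 reads expected, 1 seen), F26D10.13 (264.8 and 51.5), clec-134 (77.7 and 1.5) and clec-157 (55.6 and 8). A constant share does not account for these 4 genes. For the set, expression in these hermaphrodites cannot be told apart from such a share. The number of genes needed to exclude a share was chosen after the values were seen. The upper quartile was 1.89 times the lower, between the 1.58 times in control male 2 and the limit of 3 set for genes regulated singly. Such a share is too small for col-95, col-101, grd-3 and C33G8.3. Rises in mutant hermaphrodites that are male-biased in controls are not shown to be a response to the loss of daf-18.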

How the results depend on the processing

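The alternatives named above as added were chosen after seeing the data, and the others before. With all libraries the counts of called genes were 2 in hermaphrodites, 0 in males, 0 for the interaction, 78 between the sexes in controls and 3 between the sexes in mutants. Leaving out libraries leaves fewer samples, and a group with 1 library is then assumed to vary like the other groups; for all other changes below the cause was not tested. In hermaphrodites limma called 0 genes with a pseudocount of 0.1, a mean of at least 5 FPKM, no intensity trend, robust empirical Bayes, limma voom or protein-coding genes alone. It called 14 without a filter on low values, 9 with quantile normalization, 44 with library weights, 702 without both doubted control libraries and 1 on the compared groups alone. In males the counts were 2 without a filter, 1 with quantile normalization and 129 without both doubted control libraries, where the interaction count was 878. Between the sexes in controls they were 291 with a pseudocount of 0.1, 24 without a filter, 2 with a mean of at least 5 FPKM, 231 with quantile normalization, 51 without an intensity trend, 50 with robust empirical Bayes, 0 with library weights or limma voom, 8897 without both doubted control libraries and 0 on the compared groups alone. Between the sexes in mutants they were 0 with a pseudocount of 0.1, a mean of at least 5 FPKM, no intensity trend, robust empirical Bayes, limma voom or protein-coding genes alone, 6 without a filter, 71 with quantile normalization, 6 with each library scaled by its own total, 10239 with library weights, 9624 without both doubted control libraries and 9701 on the compared groups alone. Leaving out 1 library at a time, the counts ran from 0 to 227 in hermaphrodites, 0 to 5584 in males, 0 to 3243 for the interaction, 0 to 3883 between the sexes in controls and 0 to 3597 between the sexes in mutants.

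The counts of called lists were 0 in all 5 comparisons with an estimated correlation and with fry over all libraries, and in hermaphrodites they ran from 11 to 17 leaving out 1 library. The daf-18 transcript level turned to -0.60 in hermaphrodites and 0.63 in males without both doubted control libraries, and leaving out 1 library it ran from -0.60 to 1.31 and from -2.31 to 0.63. Genes shared in direction between the sexes numbered 23 without both doubted control libraries, or 9 with at least a 2-fold difference, against 0 with all libraries. Of the lists called with all libraries, the following turned in camera's direction without both doubted control libraries. Their medians are given, with the range over leaving out 1 library in brackets. In hermaphrodites they were major sperm proteins -0.10 (-0.10 to 1.802) and oocyte genes -0.082 (-0.082 to 2.42). In males they were DAF-16 class I genes -0.087 (-0.087 to 1.54), vitellogenins 0.16 (-3.27 to 0.16), major sperm proteins -0.64 (-0.64 to 3.76), sperm genes -0.26 (-0.26 to 3.18), oocyte genes 0.44 (-3.04 to 0.44), general germline genes 0.28 (-1.39 to 0.28), cell cycle genes 0.26 (-2.24 to 0.26), innate immune genes -0.29 (-0.31 to 1.25) and sex determination genes 0.22 (-1.19 to 0.22). For the interaction they were DAF-16 class I genes -0.21 (-0.27 to 1.88), sperm genes -0.29 (-0.55 to 2.90), oocyte genes 0.66, general germline genes 0.49 (-1.53 to 0.085), cell cycle genes 0.56 (-2.55 to -0.014), moulting genes -0.41, innate immune genes -0.43 (-0.26 to 1.32) and the mitochondrial genome -0.26. Between the sexes in controls they were vitellogenins -0.39 and the intestine 0.25. Leaving out 1 library also turned, in camera's direction, collagens in males (-0.94 to 0.53) and for the interaction (-0.71 to 0.85), and between the sexes in controls major sperm proteins (-0.55 to 3.84), sperm genes (-0.44 to 2.95) and ribosomal proteins (-0.32 to 0.13). Without both doubted control libraries the collagen median for the interaction went from 0.07 to -0.95 and the ribosomal median between the sexes in controls from -0.11 to 0.026, with no turn in camera's direction. Among lists not called with all libraries, the median changed sign without both doubted control libraries in 10 of 21 in hermaphrodites, 10 of 18 in males, 13 of 17 for the interaction, 7 of 16 between the sexes in controls and 0 of 14 between the sexes in mutants. Between the sexes in controls these include oocyte genes (0.705 to -2.55), cell cycle genes (0.225 to -1.61) and general germline genes (0.117 to -1.12).

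Of the named genes, 4 turned without both doubted control libraries and passed the threshold there: daf-18 in hermaphrodites (-0.60), and in males glp-1 (1.21), nspa-7 (-2.93) and hsp-16.2 (-1.90). Apart from leaving out 1 library, 1403 values of named genes kept their direction and their side of the threshold, 150 passed it newly, 76 no longer passed it, 8 changed sign with neither value past the threshold and those 4 turned. Of the 8, 5 were in males without both doubted control libraries, daf-18 (0.63), cey-2 (0.19), cpg-1 (0.25), vit-3 (0.24) and rnr-2 (0.24), and 3 were collagens in males, col-138 with quantile normalization (0.01) and scaling by own total (0.08) and col-14 with the latter (0.05). For lists 463 kept camera's direction and their call, 31 lost their call and 21 turned in direction. Leaving out 1 library, 819 values of named genes stayed, 109 passed newly, 70 no longer passed and 20 changed sign with neither value past the threshold, and for lists 514 stayed, 57 lost their call and 21 turned. Scaling each library by its own total moved the median of all genes by 0.17 in hermaphrodites and 0.16 in males on the log2 scale. Changes given here are relative to the median of all genes under the deposited scaling. No called list turned in camera's direction under a scaling alternative, but the collagen median for the interaction was -0.19 with quantile normalization. No paired analysis was possible, since the columns do not name their labelled replicate. The interaction uses all 4 groups, so it has no value on the compared groups alone. 21U-RNA genes called from 3 to 5 reads are at the limit of the depth.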

Other observations

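No result in this part was planned, all were looked at after their values were seen, and no explanation was tested. Neighbours of F15E11.15 on chromosome V went with it in opposite directions in the sexes. F15E11.15 (2324510 to 2325152) stood at 180 and 191 FPKM in the libraries labelled control hermaphrodite 1 and 2 and at 45.1 ± 0.268 FPKM (SD, n = 2) in mutant hermaphrodites, while mutant males held 330.1 ± 1.97 FPKM against 141.6 and 62.3 FPKM in control males. F15E11.12 (2326679 to 2327262) stood at 58.3 and 93.6 FPKM in control hermaphrodites, 16.99 ± 0.188 FPKM in mutant hermaphrodites, 68.8 and 20.7 FPKM in control males and 135.7 ± 6.62 FPKM in mutant males. F15E11.14 (2323014 to 2323524) and F15E11.13 (2330429 to 2330930) stood at 13.2 ± 1.12 and 8.81 ± 0.244 FPKM in mutant hermaphrodites and at 38.9 ± 5.88 and 30.1 ± 3.10 FPKM in mutant males. With all libraries the interaction of the 4 genes was 3.82 ± 0.61, 3.87 ± 0.83, 2.48 ± 0.78 and 1.97 ± 0.78, each with an adjusted p = 0.723. Without the doubted control libraries it was 3.19 ± 0.13 (adjusted p = 0.00109), 2.69 ± 0.15 (0.00224), 2.59 ± 0.24 (0.00969) and 1.48 ± 0.21 (0.0272).

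C33G8.2 (chromosome V, 7009761 to 7012244), next to C33G8.3, stood at 106.5 ± 12.09 FPKM in mutant hermaphrodites, 4.67 and 3.33 FPKM in the libraries labelled control hermaphrodite 1 and 2, 17.6 and 7.65 FPKM in control males and 19.04 ± 6.27 FPKM in mutant males. Its log2 difference in hermaphrodites was 4.43 (adjusted p = 0.0964), and 4.24 without the doubted control libraries (adjusted p = 0.00209). C33G8.4, on the other side of C33G8.3, stood at 33.1 ± 1.51 FPKM in mutant hermaphrodites and at 35.03 and 36.3 FPKM in their controls. col-95, col-101, grd-3 and F41E6.15 stood in mutant hermaphrodites at 537, 830.2, 124.9 and 23.9 FPKM on average, and in mutant males at 954, 2051, 276 and 53.4 FPKM.

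Genes under 0.1 FPKM in 1 library and at 5 FPKM or more in the other 7 numbered 7 in control hermaphrodite 2, 2 in control male 1, 1 in control hermaphrodite 1 and 0 in the other 5 libraries. The 2 in control male 1 lie near each other on chromosome II. T04B8.5 (614767 to 621315) had 0 reads there and 568 to 2312 reads elsewhere, and nhl-3 (595204 to 600840) had 3 reads there and 214 to 414 elsewhere. W04H10.1 (609071 to 609332), between them, had 0 reads in both control male libraries and 15 and 18 in mutant males. Outside them W08F4.3 and K07E8.7 stood in control male 1 at 84.8 and 13.6 FPKM. sfxn-1.2 had 1 and 2 reads in mutant males, and F37H8.5 next to it stood there at 89.96 ± 13.4 FPKM.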
